A study of Mus musculus with 16 samples.

How the data were processed

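RNA was sequenced from macrophages sorted by flow cytometry from C57BL/6 mice 8 weeks of age. The 16 libraries fell into 4 groups of 4: macrophages of the pericardial, pleural and peritoneal cavities, collected by lavage, and macrophages of the heart. Each library took its group and its replicate number, from 2 to 5, from its title. Per the labels' protocols, cells were sorted into TRIzol and flash frozen, RNA was purified with a Direct-zol kit, and libraries were made with a NEBNext Ultra II RNA kit. The sort gates, the way heart tissue was dissociated, the gene annotation, and the handling of strand and of reads with several hits are not given in the sources used here.

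Per the submitters' processing notes, the tools were bcl2fastq 2.17.1, TopHat2 2.1.1 and Partek 7.18.0723, with the mouse genome build mm10. Per the file headers, reads were mapped to mm10 with TopHat and the RPKM values were made in Partek. The deposited table holds RPKM (reads per kilobase of transcript, scaled to a read total of the library) for 24981 genes, each listed once, in each library. Which read total served is not given. The authors also deposited the count of alignments of each library. A further table by the authors gives comparisons with the pericardial group for 42551 transcripts. Per the file headers it holds the group mean of log2 RPKM, a ratio, a signed fold change (a score that is the negative reciprocal for ratios below 1), and p-values and q-values from an analysis of variance in Partek. For 16685 genes with 1 transcript, the authors' log2 means equalled the mean of log2(RPKM + 0.1) computed here, with a largest difference of 5.1e-05, in the pericardial group.

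From the deposited RPKM values, log2(RPKM + 0.5) was computed for the 11234 genes with an RPKM of at least 1 in at least 4 libraries. A fold change on this scale understates the change of low genes. A count test was not used, since the values are not counts. limma 3.58.1 in R 4.3.3 was fitted to all 16 libraries with 1 mean per group and a trended empirical Bayes variance, leaving 12 residual degrees of freedom per gene. Its moderated two-sided test was used for the 6 pairwise comparisons, with Benjamini-Hochberg adjustment over the 11234 genes, and a gene was called at an adjusted p under 0.05. Errors of log2 folds are limma's standard errors (SE), and errors of RPKM means are SD over 4 libraries. Genes that set 1 population apart from the other 3 were found with an intersection-union test, which takes the largest of the 3 pairwise p-values where all 3 folds have the same sign. Library similarity was described with correlations across genes and principal components, without a test.

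Altogether 35 gene lists were fixed, 21 of gene programmes and 14 of markers of other cells that a sort could hold. The programme lists were large cavity macrophage, small cavity macrophage, resident cardiac macrophage and macrophage core genes, tissue macrophage transcription factors, MHC class II antigen presentation, complement, coagulation and fibrinolysis, chemokines and cytokines, growth factors and matrix remodelling, phagocytosis and efferocytosis receptors, adhesion molecules, retinoid metabolism, cell cycle, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, lipid handling, iron and haem handling, interferon response, and immediate early and heat shock genes. The other lists were markers of monocytes, dendritic cells, B cells, T and NK cells, neutrophils, mast cells, eosinophils, cardiomyocytes, fibroblasts, endothelial, mesothelial, mural and erythroid cells and adipocytes. Lists with at least 5 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. camera compares the test statistics of a list with those of all other tested genes. Its direction, and a list called higher or lower by camera, is thus relative to those genes and not to 0. It can differ from the sign of the median or mean fold. camera with an estimated correlation and fry were alternatives. Some genes stand in more than 1 list. The tests, lists, alternatives and the naming rule were chosen before the data were examined.

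Named genes were drawn from those given by a fixed rule, and not every gene it gave is reported. In each comparison it took the 6 called genes with the largest rise and the 6 with the largest fall among genes whose groups did not overlap, leaving out predicted genes and small RNAs. In each list described it took up to 4 called members with the largest change, or, where none was called, the 2 with the highest RPKM. For genes set apart it took 8 higher and 3 lower. Gata6, Timd4, Icam2, Adgre1, Ccr2, Lyve1, H2-Aa and Cd74 were always included. Which lists had their members named in which comparison was settled after values were seen. Globin genes (Hba-a1 and Hba-a2, Hbb-b1 and Hbb-bs, Hbb-b2 and Hbb-bt) and Hspa1a and Hspa1b are near-identical pairs, so how reads were split within a pair is uncertain. Members of a pair are not independent in counts and list tests. Hbb-b1 and Hbb-b2 have no position in GENCODE M21. Genes with exons that overlap an antisense gene, Gata6 and Prg4 among them, cannot be told from their partner without strand. Positions come from GENCODE M21 on GRCm38, the assembly behind mm10.

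Alignments ranged from 40886702 to 70166356 per library. To describe library quality, the exonic share of each library was estimated as the sum over genes of RPKM times transcript length. It is a percentage of the read total behind RPKM, which did not follow the alignment count. Depth relative to pericardial library 2, read from the lowest RPKM values, was 1.16 in heart library 2 and 1.05 in peritoneal library 4. By alignments it was 1.58 and 1.31. The share is therefore relative to an unknown total. Lengths came from GENCODE M21 for 24282 genes matched by RefSeq identifier and 419 by symbol, and 280 had none. The mean RPKM of olfactory receptor genes, which macrophages do not transcribe, served as the background of each library.

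Alternatives fixed beforehand were pseudocounts of 0.1 and 1, no expression filter, a filter at RPKM 5, median-ratio scaling, quantile normalization, the highest entry per gene symbol, fits on 2 groups only, no variance trend, the replicate number as a block, and each library left out in turn. Added after the data were seen were scaling to an equal RPKM total, the background as a covariate, the fit without the 2 cavity libraries of lowest exonic share, gene lists under median-ratio scaling, the erythroid list with identical genes counted once, and a fit of the pericardial and pleural libraries alone with the replicate number as a block, alone and with the background as a covariate. Gene lists in that fit and without pleural library 3 were added too. Whether the numbers pair libraries was checked with correlations of deviations from the group means: all 4 same-numbered pericardial and pleural pairs lay above 0.1 (0.194 to 0.63), each closest to its own number, and in no other pair of groups did all 4. The labels do not say what the number marks, so this pairing comes from the data, and a low correlation does not exclude pairing in the other groups.

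The fit was tested on simulated data in which 200 genes were changed. A log2 change of 1 was recovered for 81.4% of the changed genes tested in pericardial against heart, 84.4% in pleural against heart, 78.7% in peritoneal against heart, 76.9% in pericardial against pleural, 81.0% in pericardial against peritoneal and 89.2% in pleural against peritoneal. A change of 0.5 was recovered for 20.0% in pericardial against pleural and for 23.1% in pericardial against peritoneal. Simulated genes varied independently, without a background shared within a library or differences in scaling, so these rates do not cover such effects. Each simulation changed 200 genes, whereas in the data limma called 7698 in pericardial against heart and 2 in pericardial against pleural. The Benjamini-Hochberg adjustment depends on the share of changed genes, so the recovery rates need not hold for these comparisons. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.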

Results

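Transcriptomes of resident macrophages from 3 serous cavities and from the heart were compared in unchallenged mice. The serous cavities are the fluid-filled spaces around the heart (pericardial), the lungs (pleural) and the abdominal organs (peritoneal), and their macrophages float in the lavage fluid, while heart macrophages sit in solid tissue. Each population was represented by 4 libraries. Alignments were 42167213, 60450274, 40886702 and 58566906 for pericardial libraries 2 to 5, 42379612, 61340862, 41709634 and 47335526 for pleural, 50987923, 56306606, 55063384 and 41495264 for peritoneal and 66544475, 58148496, 70166356 and 57029340 for heart libraries. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between these libraries. Lysozyme 2 (Lyz2), a macrophage secretory product, held between 6.83% and 9.38% of the RPKM total in cavity libraries and between 1.64% and 2.07% in heart libraries. The estimated exonic share was 80.3% ± 9.99 (SD, n = 4) in pericardial, 73.1% ± 3.86 in pleural, 74.5% ± 13.8 in peritoneal and 55.7% ± 7.93 in heart libraries. It was lowest in peritoneal library 4 among cavity libraries, at 55.6%, and in heart library 2 among heart libraries, at 47.4%.

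How the 4 populations lay with respect to each other was described first. The mean correlation across genes was 0.985 between pericardial and pleural libraries, against 0.984 among pericardial and 0.989 among pleural libraries. Pericardial and pleural libraries correlated with peritoneal ones at 0.974 and 0.976, and peritoneal libraries with each other at 0.975. Correlations with heart libraries were 0.783 for pericardial, 0.789 for pleural and 0.766 for peritoneal, and heart libraries reached 0.973 among themselves. Genes are not independent replicates, so these values are descriptive. The first principal component held 77.7% of the variance, the second 10.6% and the third 3.4%.

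**Figure D1:**
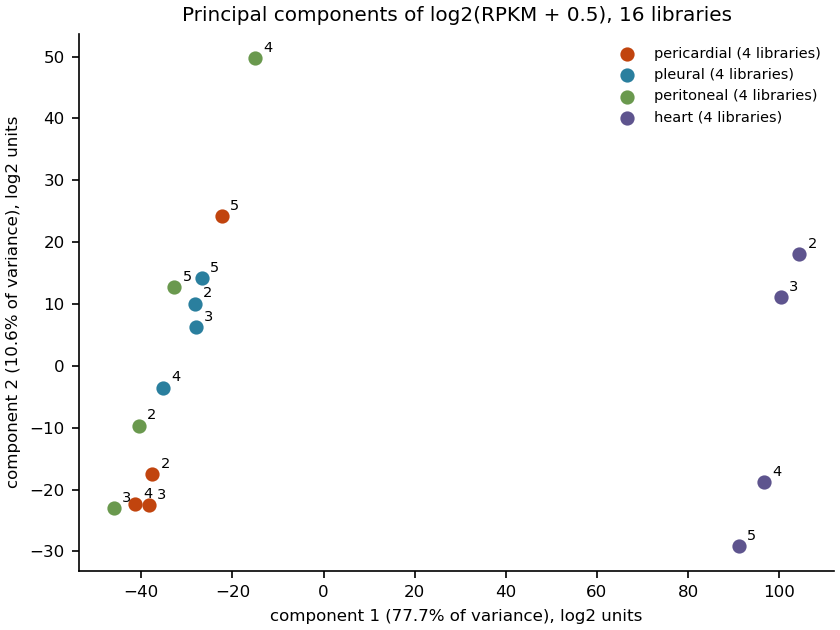
Scores of the 16 libraries on the first and second principal components of centred log2(RPKM + 0.5), in log2 units, with 1 point per library coloured by population. The first axis, with 77.7% of the variance, parts the heart libraries from the 12 cavity libraries.

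The comparison of pericardial with heart macrophages asked how cells of the cavity around the heart differ from those within its tissue. All 26 tested large cavity macrophage genes were higher in pericardial cells, with a median log2 fold of 5.05. Gata6, the transcription factor of cavity macrophages, was at 40.8 ± 8.52 RPKM against 0.841 ± 0.526 in heart (SD, n = 4 each; limma adjusted p = 2.15e-13). The adhesion molecule Icam2 rose by 6.59 ± 0.20 on the log2 scale (SE), the phosphatidylserine receptor Timd4 by 1.83 ± 0.18 and Adgre1, which encodes F4/80, by 1.29 ± 0.20. Lubricin (Prg4), the lipoxygenase Alox15 and the acute phase gene Saa3 rose by 7.42 ± 0.23, 7.42 ± 0.20 and 7.04 ± 0.32, and Serpinb2 by 6.96 ± 0.18. Conversely, 17 of 19 resident cardiac macrophage genes were lower and 2 higher, with a median of -4.06: the hyaluronan receptor Lyve1 stood at 12.5 ± 7.22 RPKM against 214 ± 41.7 in heart (-4.18 ± 0.36), the mannose receptor Mrc1 at -5.22 ± 0.33, the fractalkine receptor Cx3cr1 at -5.53 ± 0.29, Hpgd at -6.79 ± 0.20 and the TAM receptor ligand Gas6 at -7.20 ± 0.32. camera gave adjusted p = 1.28e-17 for the cavity list and 1.12e-15 for the cardiac list, and adjusted p = 0.087 for both with an estimated correlation.

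Antigen presentation genes were lower in pericardial macrophages. Of 15 MHC class II genes tested, 9 were lower and 3 higher (camera adjusted p = 1.57e-05; adjusted p = 0.31 with an estimated correlation). H2-Aa was at 179 ± 89.5 RPKM against 2335 ± 879 in heart (log2 fold -3.76 ± 0.51), and Cd74, the invariant chain, at 414 ± 184 against 4639 ± 1541 (-3.53 ± 0.49). H2-Eb1 (-4.00), H2-Ab1 (-3.59) and the activation marker Cd83 (-7.28) also fell. Of 27 chemokine and cytokine genes, 19 were lower and 4 higher (camera adjusted p = 1.18e-13; adjusted p = 0.087 with an estimated correlation). Il1b (-7.95), Ccl4 (-7.77), Ccl12 (-7.46) and Ccl7 (-7.31) fell most. Population and harvest coincided in comparisons with heart, so handling before lysis could not be told from population for these genes or Cd83. Ccr2, the receptor of monocyte chemoattractants, was slightly lower in pericardial cells (21.8 ± 4.70 against 32.2 ± 8.05 RPKM; -0.54 ± 0.22, limma adjusted p = 0.0333), a limma call lost without pericardial library 2 (adjusted p = 0.107) or 5 (0.0795) or heart library 4 (0.108) or 5 (0.0876). The 12 small cavity macrophage genes comprised 9 lower, among them the lectin Mgl2 (-4.30), Fcrls (-4.12), Itgax (-2.85) and Ear2 (-2.53), and 2 higher (camera adjusted p = 1.79e-06; adjusted p = 0.158 with an estimated correlation).

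Immediate early and heat shock genes were the list with the smallest camera p in this comparison. Of 25 tested, 24 were lower in pericardial than in heart macrophages and 1 was higher, with a median log2 fold of -3.19 (camera adjusted p = 9.58e-26; adjusted p = 0.0759 with an estimated correlation). Fosb was at 0.378 ± 0.0758 RPKM against 408 ± 143 in heart (-8.79 ± 0.19), and Egr1 (-7.22), Egr2 (-6.23) and Atf3 (-5.58) fell as well. Of 25 transcription factors of tissue macrophages, 14 were lower, including Nr4a1 (-4.68) and the haem-responsive Spic (-4.41), and 5 were higher, including Nfe2 (5.58) and Gata6 (camera adjusted p = 2.71e-05; adjusted p = 0.386 with an estimated correlation). Iron and haem genes were lower for 10 of 18 and higher for 5 (camera adjusted p = 9.52e-05; adjusted p = 0.386 with an estimated correlation). The iron exporter Slc40a1 (-5.23), the haemoglobin scavenger receptor Cd163 (-4.90) and haem oxygenase Hmox1 (-2.82) fell. Among 25 interferon response genes 14 were lower and 1 higher (camera adjusted p = 1.78e-07; adjusted p = 0.386 with an estimated correlation), with Cxcl10 at -4.94, Ifit3 at -3.86, Ifit2 at -2.89 and Rsad2 at -2.11.

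Coagulation, adhesion and matrix genes moved both ways. Coagulation factors V (F5, 6.85 ± 0.19) and VII (F7, 6.45 ± 0.18) and the plasminogen activator inhibitor Serpinb2 were among 7 of 15 coagulation genes higher in pericardial cells, and Gas6 among 5 lower. The adhesion list had 14 of 22 higher, led by P-selectin (Selp, 6.84), Icam2, Cd24a (5.54) and Itga6 (4.83), and 6 lower (camera adjusted p = 0.125). Growth factor and matrix genes comprised 10 higher, among them fibronectin (Fn1, 7.31), Ltbp1 (6.30) and Thbs1 (6.10), and 16 lower, among them the collagenase Mmp13 (-6.07); camera gave adjusted p = 0.000123, and adjusted p = 0.158 with an estimated correlation. Of 23 phagocytosis receptors 12 were higher, with Marco at 5.11, and 7 lower, with Itgb5 at -6.05 and Mrc1 at -5.22. Complement genes were higher for 8 of 19, led by Cfb (3.94), C4b (3.74), Itgam (3.68) and Cfp (3.48), and lower for 5. Of 11 retinoid genes 7 were higher, including the receptor Rarb (3.58) and the retinaldehyde dehydrogenase Aldh1a2 (2.81), and 1 was lower, Aldh1a1 (-2.20; camera adjusted p = 0.253). Macrophage core genes were divided, with 7 of 20 higher (Itgam; Lyz2, 2.78; Ctsd, 2.29) and 7 lower (Aif1, -4.28). camera called none of the coagulation, complement, phagocytosis and core lists (adjusted p = 0.838, 0.84, 0.661 and 0.192) and gave each a downward direction; the mean fold was above 0 for coagulation (0.86), complement (0.66) and core genes (0.15) but -0.13 for phagocytosis, and the median was above 0 for all but the core list (0.18, 0.36 and 0.74, against -0.05). Under median-ratio scaling camera turned upward for coagulation, complement and phagocytosis (adjusted p = 0.787, 0.949 and 0.826), while the coagulation and complement medians passed below 0 (-0.06 and -0.01).

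Metabolic and cell cycle genes were mostly higher in pericardial cells on the deposited scale. Of 30 oxidative phosphorylation genes, 29 were higher and none lower (camera adjusted p = 0.00271; adjusted p = 0.727 with an estimated correlation), led by Ndufa1 (2.32 ± 0.20) and Ndufa4 (1.75 ± 0.21). Of 30 cell cycle genes, 27 were higher and none lower, with Rrm2 at 1.46 ± 0.19 and Cdca8 at 1.31 ± 0.27, a call lost at an equal RPKM total (limma adjusted p = 0.0728; camera adjusted p = 0.0156; adjusted p = 0.727 with an estimated correlation). With libraries scaled to an equal RPKM total these counts were 16 and 9 higher and 0 and 1 lower. Glycolysis genes were higher for 13 of 18, with the phosphofructokinase Pfkl at 2.76 and the lactate transporter Slc16a3 at 2.29, and lower for 2 (camera adjusted p = 0.068). Cholesterol synthesis genes were higher for 15 of 20 and lower for 0 (camera adjusted p = 0.068), but 5 higher and 2 lower at an equal RPKM total. Lipid handling genes were higher for 13 of 25, led by Fabp4 (5.38) and Apoc2 (4.31), and lower for 6, with Fabp3 at -3.79 (camera adjusted p = 0.889).

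Markers of other cells separated the heart libraries as well. Summed cardiomyocyte marker RPKM was 582 ± 173 in heart against 3.82 ± 0.691 in pericardial, 4.92 ± 0.654 in pleural and 4.55 ± 0.616 in peritoneal libraries. Of 14 tested, 13 were lower in pericardial cells, with myosin light chain Myl2 at -7.85 ± 0.17 and myoglobin (Mb) at -7.55 ± 0.16 (camera adjusted p = 5.34e-19; adjusted p = 0.0759 with an estimated correlation). All 10 fibroblast markers were lower, with decorin (Dcn) at -6.49 (camera adjusted p = 2.49e-13; adjusted p = 0.112 with an estimated correlation). Of 27 cardiomyocyte and fibroblast markers in the data, 26 were higher in every heart library than in every cavity library. Chance gives this order for 0.0549% of genes where groups do not differ. Many genes differed here, with 1298 of 11234 set apart as higher in heart by the intersection-union test. The share of all genes with this order was not computed. The endothelial marker Aqp1 (-3.24) and the mural cell markers Des (-3.21) and Rgs5 (-2.14) were also lower in pericardial cells. B cell markers were higher in pericardial cells for 7 of 10 and lower for 0, with Cd79a at 3.25 ± 0.46 (camera adjusted p = 0.157). Monocyte markers were higher for 6 of 12 (7 adjusted over the list alone), with haptoglobin (Hp) at 6.17, and lower for 5 (camera adjusted p = 0.91, in a downward direction although the median was 1.36 and the mean 1.23). Dendritic cell markers were lower for 2 of 6 (Batf3, -1.06; camera adjusted p = 0.0334; adjusted p = 0.164 with an estimated correlation). The erythroid list was lower with 1 called member, Alas2 (-0.97), and none adjusted over the list alone (camera adjusted p = 0.024; adjusted p = 0.67 with an estimated correlation). The Alas2 call was lost without pericardial library 4 or 5 or heart library 3 or 5 (limma adjusted p from 0.0762 to 0.141), with 2 groups only (0.0615) and with the background as a covariate (0.0704). Lists too short for camera were neutrophil markers (2 of 3 higher, 1 lower), mast cell markers (Hdc higher, 3 lower) and eosinophil markers (Alox15 higher, 1 not called). T and NK cell, mesothelial and adipocyte markers had 0 members above the expression filter.

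**Figure D2:**
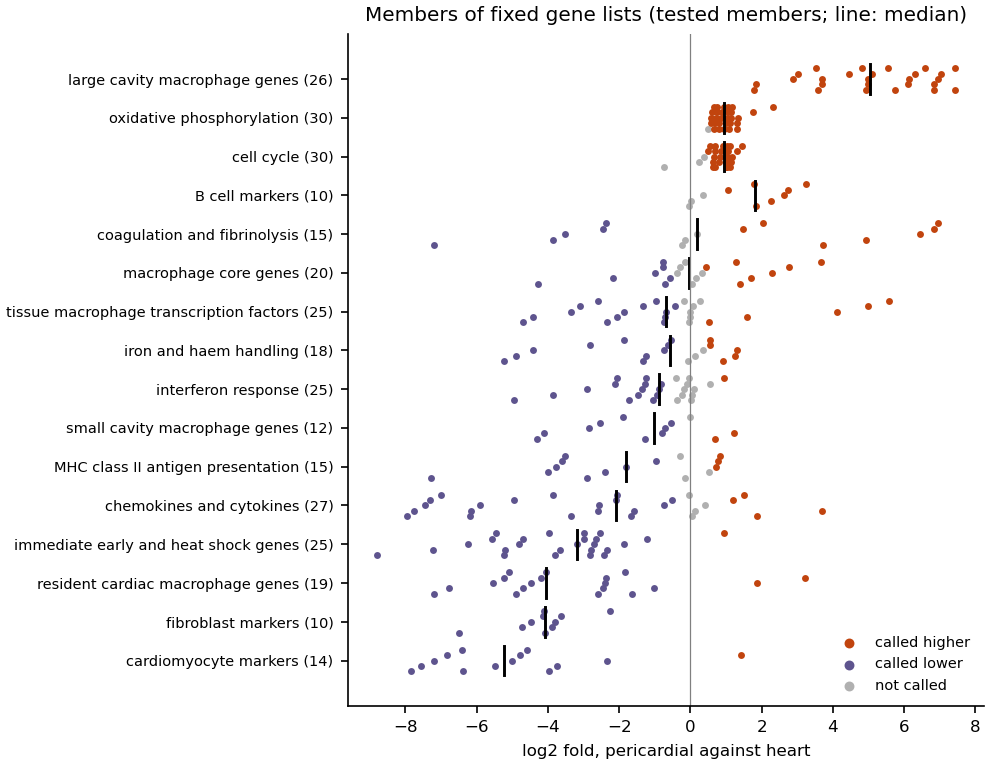
Log2 fold of pericardial against heart macrophages on the horizontal axis for each tested member of 16 gene lists, with 1 point per gene coloured by whether limma called it, and a line at the median of each list. The large cavity list lies above 0 with a median of 5.05 and the immediate early and heat shock list mostly below 0 with a median of -3.19.

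In all, limma called 7698 of 11234 genes in pericardial against heart macrophages, 6048 higher and 1650 lower. The called genes of largest rise were Slpi, Prg4, Alox15, Fn1, Cd5l and Saa3 (7.04 to 7.52) and those of largest fall Fosb, Il1b, Myl2, Ccl4, Mb and Ccl12. The split depended on how libraries were scaled, as RPKM totals ranged from 227397 in heart library 2 to 482872 in pericardial library 3: 4409 higher and 2833 lower with median-ratio scaling, 4489 and 2865 with quantile normalization, and 2694 and 4070 at an equal RPKM total. The median log2 fold over all genes moved from 0.45 to 0.12, 0.13 and -0.12. Members adjusted over the list alone numbered the same as over all genes except for monocyte and erythroid markers, as given, and oxidative phosphorylation (30 higher).

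The same question was put to pleural and peritoneal macrophages. All 26 large cavity genes were higher than in heart in each of these comparisons, with medians of 5.09 in pleural and 5.13 in peritoneal cells, and 17 of 19 cardiac macrophage genes were lower. Gata6 stood at 34.1 ± 2.19 RPKM in pleural and 41.0 ± 8.67 in peritoneal cells (limma adjusted p = 4.55e-13 and 1.97e-13), and Icam2 rose by 6.48 ± 0.20 and 6.05 ± 0.20. Lyve1 (-5.03 and -3.66) and Mrc1 (-5.45 and -5.97) fell. Timd4 rose by 1.74 and 1.76 and Adgre1 by 1.12 and 1.39, while Ccr2 was lower at 15.8 ± 3.89 RPKM in pleural (limma adjusted p = 0.000592) and 7.31 ± 1.63 in peritoneal cells (-2.06). camera gave adjusted p = 3.38e-19 and 9.53e-19 for the cavity list and 2.37e-16 and 5.89e-15 for the cardiac list. Both lists had adjusted p = 0.0705 in pleural and 0.0714 in peritoneal cells with an estimated correlation.

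MHC class II genes were lower than in heart for 9 of 15 in pleural cells (2 higher, 3 adjusted over the list alone; camera adjusted p = 1.91e-05; adjusted p = 0.323 with an estimated correlation) and for 10 of 15 in peritoneal cells (2 higher; 4.87e-07; adjusted p = 0.185 with an estimated correlation). H2-Aa (-3.83 in pleural, -4.84 in peritoneal cells) and Cd74 (-3.58 and -4.60) fell. Immediate early and heat shock genes were lower for 24 of 25 and higher for 1 in each (camera adjusted p = 5.44e-28 and 1.37e-28; adjusted p = 0.0705 and 0.0714 with an estimated correlation), with Fosb at -8.10 and -9.14, Fos at -7.08 and -8.23 and Hspa1a at -6.52 and -8.37. Haemoglobin and other erythroid genes were lower for 7 of 7 in both. Hbb-b1 stood at 213 ± 102 RPKM in heart, 50.2 ± 20.3 in pleural and 0.916 ± 0.746 in peritoneal libraries, with Hba-a1 at -2.52 in pleural and Hbb-b1 at -7.28 in peritoneal cells (camera adjusted p = 0.000302 and 1.66e-08; adjusted p = 0.345 and 0.106 with an estimated correlation). limma called 6933 genes in pleural against heart, 5366 higher and 1567 lower, and 7071 in peritoneal against heart, 5485 higher and 1586 lower. With median-ratio scaling the splits were 3963 and 2774, and 4116 and 2689; with quantile normalization 4290 and 2787, and 4347 and 2776; at an equal RPKM total 2709 and 3689, and 3470 and 3080. The median log2 fold moved from 0.36 to 0.08, 0.10 and -0.11 in pleural and from 0.38 to 0.10, 0.11 and 0.01 in peritoneal cells. camera called 15 and 16 of 27 lists, against 16 in pericardial against heart. Largest among rises were Slpi (7.38), Alox15 (7.28), Saa3 (7.09), Prg4 (7.06), Cd5l (7.02) and Fn1 (6.85) in pleural and Arg1 (7.88), Cd5l (7.60), Fn1 (7.58), Slpi (7.51), Saa3 (7.32) and Prg4 (7.32) in peritoneal cells. Among falls stood Il1b (-7.42 and -8.10), Ccl2 (-7.45 and -8.04) and Myl2 (-7.34 and -7.84).

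Genes that set heart macrophages apart from all 3 cavity populations numbered 5908 in the intersection-union test, 1298 higher and 4610 lower in heart. The split was 2171 and 3183 with median-ratio scaling and 2319 and 3544 with quantile normalization, and at an equal RPKM total the majority turned, with 2765 higher and 2250 lower. Those highest by their smallest fold were Fosb (8.10), Il1b (7.42), Ccl4 (7.40), Myl2 (7.34), Egr1 (7.22), Ccl7 (7.14), Mb (7.11) and Cd83 (7.01), so that cardiomyocyte genes stood among immediate early and inflammatory genes. The lowest were the protease inhibitor Slpi (-7.38), Alox15 (-7.16) and Prg4 (-7.06). Fosb lies on chromosome 7 from 19302696 to 19310051 and Slpi on chromosome 2 from 164354070 to 164389095 (GRCm38).

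**Figure D3:**
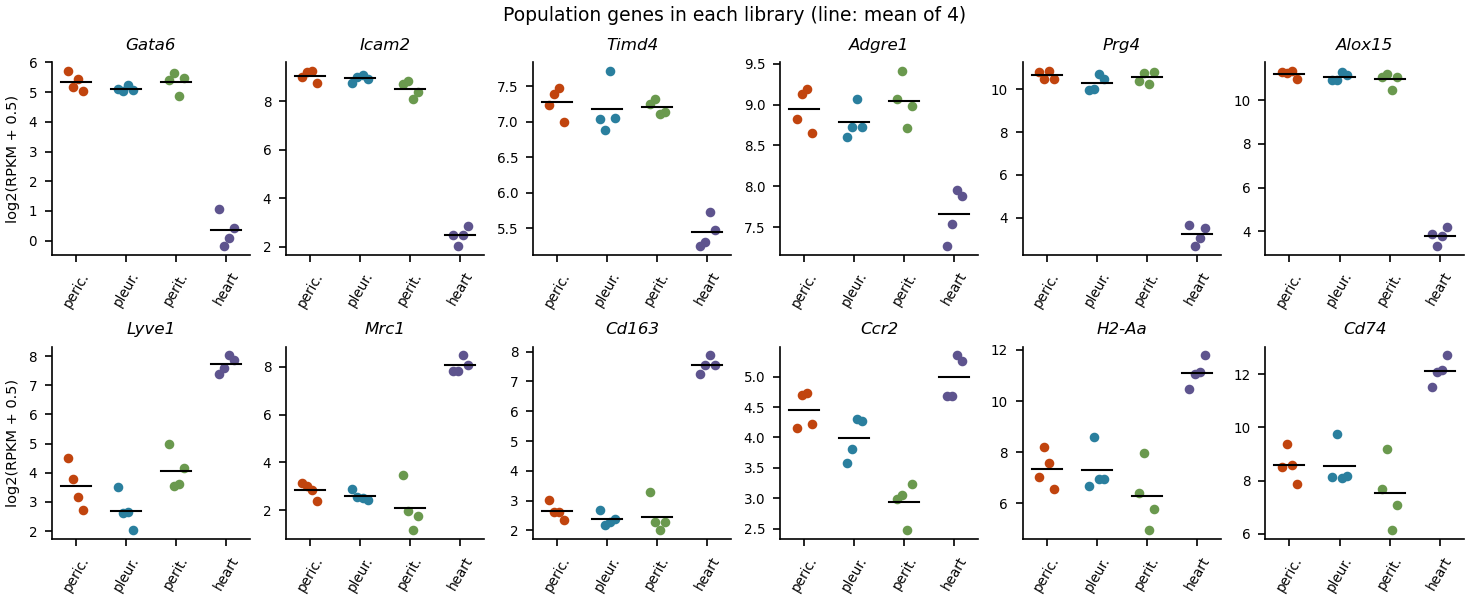
Expression of 12 genes in log2(RPKM + 0.5) on the vertical axis, with 1 point per library in each of the 4 populations and a line at the mean of 4 libraries. Gata6 averaged between 34.1 and 41.0 RPKM in the cavity populations and 0.841 in heart, and Lyve1 between 6.43 and 17.8 against 214.

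Pericardial and peritoneal macrophages, the next pair, shared the cavity programme but differed in arginase and globin transcripts. Globins belong to the erythroid markers of other cells, whose sum ranged from 87.0 to 1120 RPKM within the pericardial libraries. Whether red cells in the samples supplied them was not tested. Arg1, which degrades arginine, was at 12.7 ± 4.40 RPKM in pericardial, 167 ± 23.4 in peritoneal and 9.90 ± 1.88 in pleural cells (pericardial against peritoneal -3.72 ± 0.20, limma adjusted p = 1.14e-09). The scavenger receptors Marco (54.1 ± 15.9 against 207 ± 49.4 RPKM; -1.94 ± 0.19, adjusted p = 4.16e-06) and Stab1 (-1.71 ± 0.18, 8.97e-06) and the signalling protein Ubash3a (-1.64 ± 0.16, 4.16e-06) were also lower. Ccr2 was higher in pericardial cells (21.8 ± 4.70 against 7.31 ± 1.63 RPKM; 1.52 ± 0.22, 0.00057). Gata6 (-0.00 ± 0.22), Timd4 (0.07 ± 0.18) and Adgre1 (-0.10 ± 0.20) were not called, nor were Icam2 (0.54 ± 0.20, adjusted p = 0.356) and Lyve1 (-0.53 ± 0.36, 0.665). Of 26 large cavity genes only Apoc1 was called (-1.35 ± 0.28; 1 higher and 1 lower adjusted over the list alone), a limma call lost without pericardial library 2 or 4 or peritoneal library 3 or 4 (adjusted p = 0.0899, 0.0515, 0.0623 and 0.0719); camera gave adjusted p = 0.92, downward against a median of 0.01 and a mean of 0.02.

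Gene lists parted this pair in several ways. Immediate early and heat shock genes were higher in pericardial cells for 12 of 25 and lower for 0 (14 higher adjusted over the list alone; camera adjusted p = 7.04e-21; adjusted p = 0.0926 with an estimated correlation), with Fos at 49.9 ± 11.1 against 6.05 ± 2.51 RPKM (3.02 ± 0.26), Hspa1a at 2.91 and Hspa1b at 2.61. The largest rises belonged to the globin genes Hbb-b1 (6.64), Hbb-bs (6.23), Hba-a2 (5.86), Hba-a1 (5.81) and Hbb-b2 and Hbb-bt (4.74 each). All 7 erythroid genes were higher (camera adjusted p = 3.12e-29), and this call was kept with an estimated correlation (adjusted p = 0.0176). Hbb-b2 and Hbb-bt had identical values in every library, and with them counted once all 6 were higher (camera adjusted p = 3.06e-25; 0.0178 with an estimated correlation). The near-identical pairs Hbb-b1 and Hbb-bs, and Hba-a1 and Hba-a2, still counted as separate members there, so the 6 are not independent. Small cavity macrophage genes were higher for 3 of 12, namely Fcrls (1.54), Ccr2 and Cd226 (0.96), and dendritic cell markers for 1 of 6, Batf3 (1.24). Adjusted over the list alone the counts were 4 higher and 1 lower, and 3 higher. camera gave adjusted p = 0.000971 for each of these lists, and adjusted p = 0.598 and 0.0832 with an estimated correlation. Cd226 was not called without any 1 of pericardial libraries 2, 3 and 4 and peritoneal libraries 2 and 4 (p from 0.0606 to 0.0962). Phagocytosis receptors were lower for 3 of 23, Marco, Stab1 and Cd93 (-0.97; not called by limma without pericardial library 2 or peritoneal library 5, adjusted p = 0.0606 and 0.0509), and higher for 0 (1 adjusted over the list alone; camera adjusted p = 0.048; adjusted p = 0.833 with an estimated correlation). Lipid handling genes were lower for 2 of 25, Apoc1 and lipoprotein lipase Lpl (-1.06 ± 0.25, adjusted p = 0.0481; 3 lower adjusted over the list alone; camera adjusted p = 0.000971; adjusted p = 0.708 with an estimated correlation). Lpl lost its call when any 1 of the 4 pericardial libraries or peritoneal library 2, 4 or 5 was left out (limma adjusted p from 0.0519 to 0.203). The call was also lost with 2 groups only (0.0562) and with a pseudocount of 0.1 (0.053).

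Cholesterol synthesis genes were higher in pericardial than in peritoneal cells by camera (adjusted p = 2.73e-07; adjusted p = 0.598 with an estimated correlation), with 1 of 20 called and 7 adjusted over the list alone. Cell cycle genes were lower by camera without a called member (5 lower adjusted over the list alone; adjusted p = 2.16e-09; adjusted p = 0.598 with an estimated correlation). Class II genes had 0 called members by limma (camera adjusted p = 0.00318; adjusted p = 0.748 with an estimated correlation), with H2-Aa at 1.08 ± 0.51 and Cd74 at 1.07 ± 0.49 (limma adjusted p = 0.562 and 0.55). B cell markers were called by camera (adjusted p = 0.00234; adjusted p = 0.665 with an estimated correlation) with Cd2 alone called (1.42 ± 0.30), a limma call lost without pericardial library 2, 3 or 4 or peritoneal library 4 or 5 (adjusted p from 0.0515 to 0.102) and with 2 groups only (0.114). The mast cell protease Mcpt4 was lower (-1.83 ± 0.42, adjusted p = 0.0381), near the expression floor at 0.0611 ± 0.0436 against 1.84 ± 1.60 RPKM, and so was sialoadhesin (Siglec1, -1.53 ± 0.35, adjusted p = 0.0357). Mcpt4 and Siglec1 lost their calls when pericardial library 2, 4 or 5 or peritoneal library 2 or 5 was left out (p from 0.0556 to 0.183). Altogether limma called 107 genes, 59 higher and 48 lower, with 999 at an unadjusted p under 0.05. At an equal RPKM total the split was 112 higher and 365 lower, with the median over all genes at -0.14. The count was 60 without pericardial library 2, and 67, 68 and 64 without pericardial library 3, pericardial library 4 and peritoneal library 5.

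**Figure D4:**
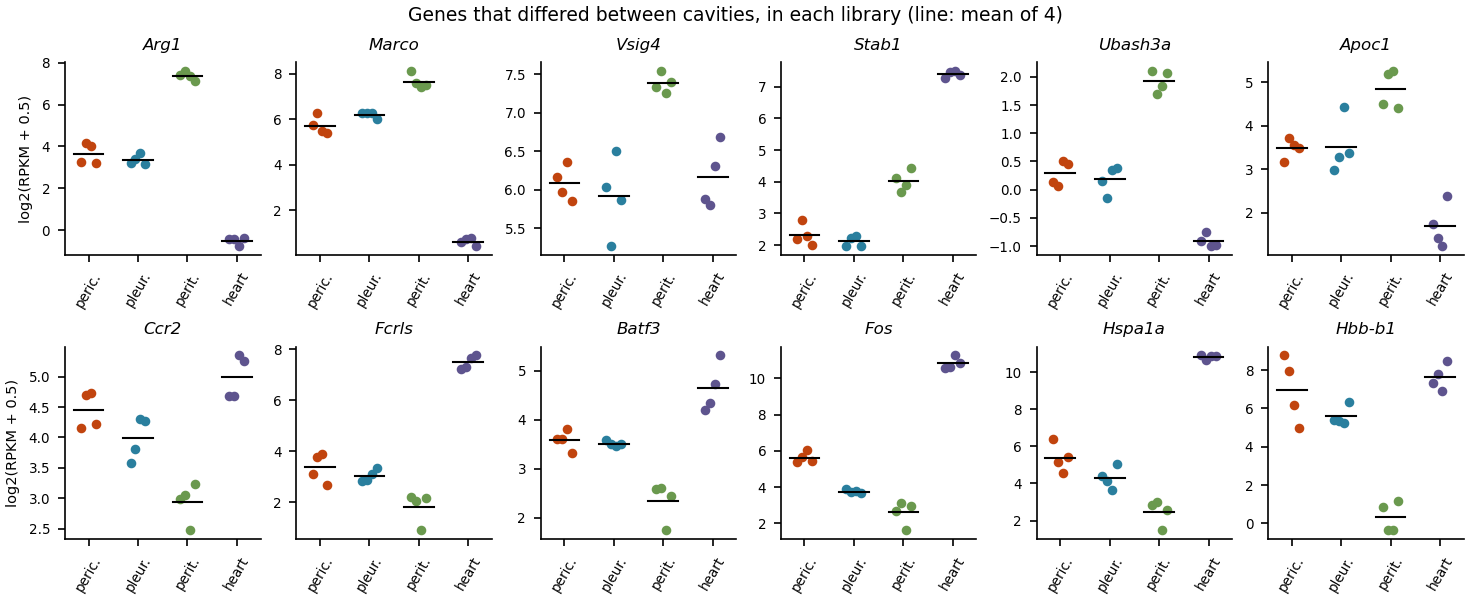
Expression of 12 genes that differed between cavity populations in log2(RPKM + 0.5) on the vertical axis, with 1 point per library and a line at the mean of 4 libraries. Arg1 averaged 167 RPKM in peritoneal cells against 12.7 in pericardial and 9.90 in pleural cells, and Hbb-b1 0.916 against 197 and 50.2.

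Pleural and peritoneal macrophages were compared next. Arg1 was lower in pleural cells by a log2 fold of -4.01 ± 0.20 (limma adjusted p = 2.81e-10), Stab1 by -1.92 ± 0.18, Ubash3a by -1.74 ± 0.16, Vsig4 by -1.47 ± 0.23 and Marco by -1.46 ± 0.19. The galactose-binding lectin Lgals1 was lower as well (16.5 ± 2.52 against 58.5 ± 19.9 RPKM; -1.75 ± 0.23). Ccr2 (1.06 ± 0.22), Batf3 (1.16 ± 0.22), Fos (1.15 ± 0.26) and Hspa1a (1.85 ± 0.35) were higher in pleural cells, and Il1a (-1.32 ± 0.27) lower. Gata6 (-0.24 ± 0.22), Timd4 (-0.03), Icam2 (0.43), Adgre1 (-0.26) and Lyve1 (-1.37 ± 0.36, adjusted p = 0.106) were not called. Apoc1 was the 1 called member of the 26 large cavity genes (-1.32; camera adjusted p = 0.318), and its limma call was lost without peritoneal library 3 or pleural library 2, 3 or 5 (adjusted p from 0.0996 to 0.134). The globin genes Hbb-b1, Hbb-bs, Hba-a1, Hba-a2, Hbb-b2 and Hbb-bt were higher by 5.25, 4.80, 4.48, 4.44, 3.37 and 3.37, and Mcpt4 lower by -1.91 (adjusted p = 0.0398). The Mcpt4 call was lost without any 1 of the 4 pleural libraries or peritoneal library 2, 3 or 5 (limma adjusted p from 0.0539 to 0.183), and that of Hspa1a without pleural library 5 (0.0678). By limma, Ccr2 was not called without peritoneal library 2 or pleural library 4 or 5 (limma adjusted p = 0.0598, 0.0928 and 0.113). Il1a was not called without pleural library 2, 3 or 5 or peritoneal library 2 or 3 (limma adjusted p from 0.054 to 0.109). Fos was not called without any 1 of the 4 pleural libraries or peritoneal library 2 (limma adjusted p from 0.0844 to 0.126).

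Among lists, 6 of 7 erythroid genes were higher in pleural cells (7 adjusted over the list alone; camera adjusted p = 3.06e-23; 0.0213 with an estimated correlation; 5 of 6 with identical genes counted once, 0.0208 with an estimated correlation) and 1 of 6 dendritic cell markers (3 adjusted over the list alone; 1.86e-05; 0.0213 with an estimated correlation). With the erythroid list in pericardial against peritoneal, these were the camera calls that held with an estimated correlation in the 6 comparisons. Near-identical globin pairs without identical values counted as separate members in each of these erythroid tests. Phagocytosis receptors were lower for 4 of 23, with Cd93 at -1.05 and Lrp1 at -0.84 (not called by limma without peritoneal library 5 or pleural library 3 or 5, adjusted p from 0.0604 to 0.0813) beside Stab1 and Marco, and higher for 0 (1 adjusted over the list alone; camera adjusted p = 0.00644; adjusted p = 0.728 with an estimated correlation). Lipid handling genes were lower for 3 of 25, Apoc1, Lpl (-1.29) and the cholesterol exporter Abca1 (-0.98; 5 adjusted over the list alone; 0.000399; adjusted p = 0.714 with an estimated correlation). Lpl was not called by limma without peritoneal library 2 or 5 or pleural library 3 or 5 (adjusted p from 0.0672 to 0.0735), and Abca1 without any 1 of peritoneal libraries 2, 3 and 5 and pleural libraries 3, 4 and 5 (from 0.0572 to 0.0978). Immediate early and heat shock genes were higher for 3 of 25 (9 adjusted over the list alone; 5.77e-08; adjusted p = 0.613 with an estimated correlation), among them Fosb (1.04 ± 0.19) at 0.926 ± 0.174 against 0.196 ± 0.0866 RPKM. The Fosb call was lost without pleural library 2 (limma adjusted p = 0.0528), with a pseudocount of 1 (0.108) and with quantile normalization (0.106). Its pleural level was 0.227% of the heart mean, beside 0.188% for Myl2 and 0.192% for Mb, and cardiomyocyte markers were higher in pleural cells by camera (adjusted p = 0.0449; adjusted p = 0.818 with an estimated correlation). Small cavity macrophage genes had 1 of 12 higher, Ccr2, and 1 lower (4 and 1 adjusted over the list alone; camera upward, adjusted p = 0.0106; adjusted p = 0.728 with an estimated correlation). Class II genes had 0 called members by limma (camera adjusted p = 8.41e-05; adjusted p = 0.613 with an estimated correlation), with Cd74 at 1.02 ± 0.49 and H2-Aa at 1.01 ± 0.51. Chemokine genes were not called by camera (adjusted p = 0.292). Altogether limma called 66 genes, 24 higher and 42 lower, with 1096 at an unadjusted p under 0.05. Median-ratio scaling gave 96 higher and 377 lower, and an equal RPKM total 110 and 634. Without peritoneal library 4, the cavity library of lowest exonic share, the count was 490 (39 higher and 451 lower), and without pleural library 5 it was 39.

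Pericardial and pleural macrophages differed least. The transcription factor Fos was higher in pericardial cells, at 49.9 ± 11.1 RPKM (log2 fold 1.87 ± 0.26, limma adjusted p = 0.00621). Gata6 (0.23 ± 0.22), Timd4 (0.10 ± 0.18), Icam2 (0.11 ± 0.20), Adgre1 (0.17 ± 0.20), Ccr2 (0.46 ± 0.22) and Lyve1 (0.85 ± 0.36) were not called, with an adjusted p of 0.968 each. Same-numbered libraries of these populations correlated, and with the number as a block in the 8 libraries alone, limma called 23 genes, 14 higher and 9 lower. Among them Lyve1 was higher (0.85 ± 0.12, adjusted p = 0.0185), as was Fos (9.26e-05), and Fosb was lower (-0.70 ± 0.12, 0.0441). Cardiomyocyte markers were lower by camera in this fit too (adjusted p = 7.36e-07, and 0.477 with an estimated correlation). Fosb is among the heart transcripts found at a low level in pleural libraries. As a set the limma calls of this blocked fit were not robust. It called 0 genes with the background as a covariate, which also left fewer degrees of freedom, and 480 with the labels of the libraries numbered 5 exchanged. Fos was also called without the block, and it kept that call with the background as a covariate in the fit of 16 libraries. H2-Aa and Cd74 lay at 0.06 ± 0.51 and 0.05 ± 0.49, and none of the 26 large cavity or 19 cardiac macrophage genes was called by limma in the fit without a block, adjusted over the list alone included. The cardiac list had camera adjusted p = 0.0992, and 0.00515 in the blocked fit of 8 libraries (adjusted p = 0.863 and 0.858 with an estimated correlation). The immediate early and heat shock list was higher by camera (1 higher by limma, 8 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.86e-13; adjusted p = 0.519 with an estimated correlation), and so was the erythroid list (0 called by limma, 6 higher adjusted over the list alone; 5.64e-08; adjusted p = 0.519 with an estimated correlation). Hbb-b1 was at 197 ± 186 RPKM in pericardial and 50.2 ± 20.3 in pleural libraries (1.39 ± 0.59, adjusted p = 0.968). Without the block limma called 2 genes, with 195 at an unadjusted p under 0.05. The other was the microRNA gene Mir3064, which the naming rule leaves out and which is named after its value was seen (-1.36 ± 0.20, adjusted p = 0.00825). A count of 4 was reached without pericardial library 5, and 1 without pericardial library 2 or 4 or pleural library 4.

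Among genes set apart, 25 parted peritoneal macrophages from the other 3 populations, 12 higher and 13 lower, with 288 at an unadjusted p under 0.05. By their smallest fold, Arg1 led at 3.72 (adjusted p = 1.14e-09), ahead of Ubash3a (1.64), Marco (1.46), the sheddase Adam8 (1.31), Ankrd37 (1.23), Vsig4 (1.22, adjusted p = 0.0235), Stard13 (1.13; limma adjusted p = 0.065 without the 2 cavity libraries of lowest exonic share) and She (1.11). Vsig4 was not called by limma under median-ratio scaling (adjusted p = 0.0846) and in 11 further alternatives. The lowest were Hbb-b1 (-5.25) and Hbb-bs (-4.80), a near-identical pair, and Hba-a1 (-4.48), all from the erythroid marker list. The intersection-union test on the limma fit set apart 0 genes for pericardial macrophages (16 at an unadjusted p under 0.05) and 0 for pleural macrophages (10). Arg1 lies on chromosome 10 from 24915221 to 24927484, Marco on chromosome 1 from 120474538 to 120505024, Fos on chromosome 12 from 85473890 to 85477273 and Gata6 on chromosome 18 from 11052064 to 11085635 (GRCm38, GENCODE M21), where Gata6 shares exon sequence with an antisense transcript.

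**Figure D5:**
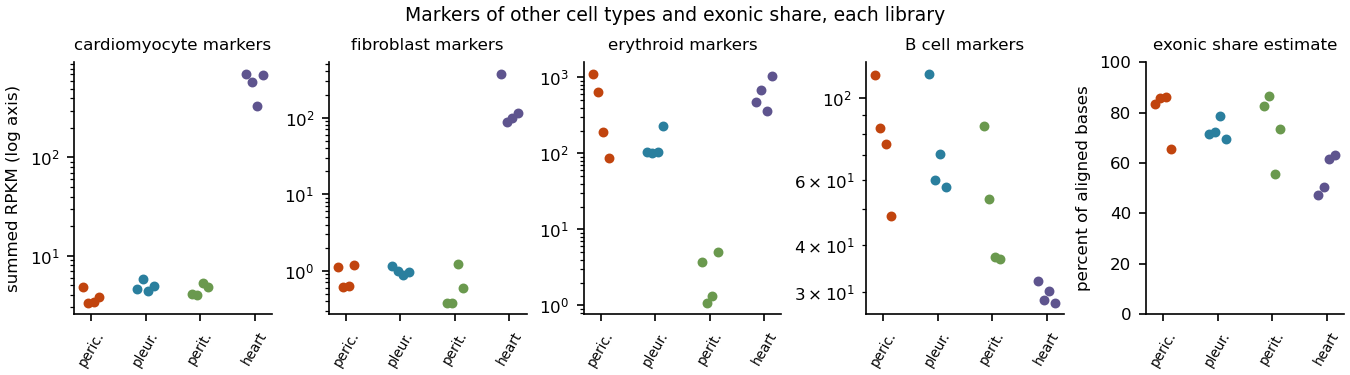
Summed RPKM of cardiomyocyte, fibroblast, erythroid and B cell markers on a log axis and estimated exonic share in percent, with 1 point per library in each of the 4 populations. Cardiomyocyte markers summed to at least 336 RPKM in heart libraries and at most 5.85 in cavity libraries, and erythroid markers averaged 2.81 in peritoneal libraries against 512 in pericardial ones.

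The authors' deposited table compared each population with the pericardial one per transcript. It lists 14970 transcripts of 10958 gene symbols at a q-value under 0.05 for heart against pericardial, 5870 higher and 9098 lower by their ratio. For peritoneal against pericardial it lists 34 transcripts of 29 symbols, 12 higher and 22 lower, and 22 of these symbols were among the 107 genes called by limma here. In the authors' deposited table the peritoneal to pericardial ratio was 13.6 for Arg1 (q = 0.000157), 3.86 for Marco (q = 0.00336) and 0.115 for Fos (q = 0.00304). For pleural against pericardial the authors' deposited table lists 0 transcripts at that q and 1099 at an unadjusted p under 0.05, and Fos has a ratio of 0.267 (q = 0.307).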

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

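Tests of unspliced RNA and genomic DNA for the exonic share were chosen before its result was seen, and the test of depth after it. Within each group of 4 libraries, the highest or lowest value was compared with its nearest neighbour by Dixon's criterion, for genes with a group mean of at least 1 RPKM, a limit set after values were seen. Of 430 groups tested over the named genes, marker sums and library measures, 22 held a value far from the other 3, and chance gives about 1 in 20. The set of genes tested was reduced afterwards to those named in the text, without Cd207, Cox8b, Csf3r, Csrp3, Ctss, Cxcr2, Cyr61, Mir3064 and Slco2b1, which were not tested.

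Class II genes stood apart in pleural library 3, and H2-Aa and Cd74 were highest in number 3 of each cavity. H2-Aa was at 382 RPKM in pleural library 3 against 103 to 123 in the other pleural libraries, H2-Ab1 at 458 against 121 to 138, H2-Eb1 at 202 against 69.6 to 78.6 and Cd74 at 860 against 273 to 289. Siglec1 was highest in number 3 of all 4 groups, and stood apart in pleural library 3, at 3.92 against 1.18 to 1.29, and in peritoneal library 3, at 11.95 against 4.23 to 4.87. It was at 3.36 against 0.990 to 1.87 in pericardial library 3 and at 22.6 against 12.8 to 17.7 in heart library 3. Ifit2 and Ifit3 were highest in number 3 of all 4 groups too, a pattern looked for after the values were seen. In pericardial library 3, H2-Aa was at 298 against 92.9 to 193 and Cd74 at 671 against 235 to 383, and in peritoneal library 3 they were at 249 against 30.4 to 83.9 and at 578 against 69.9 to 204. Pleural library 5 was highest in erythroid marker RPKM (228 against 101 to 106), with Hbb-b1 at 80.6 against 37.6 to 42.1 and Hbb-bs at 42.9 against 20.02 to 22.4, and lowest in Marco (64.0 against 76.8 to 77.4). Hspa1b was lowest in pleural library 4 (13.2 against 39.3 to 44.5). In peritoneal library 4, Adam8 (50.7 against 72.4 to 75.7) and Fcrls (1.36 against 3.65 to 4.06) were lowest. In heart library 4, Cd83 (376 against 139 to 147), Egr2 (99.99 against 59.2 to 62.8) and the sum of monocyte markers (356 against 225 to 234) were highest. Nr4a1, which also stands in the immediate early list, held 195.5 ± 62.5 RPKM of the mean heart monocyte sum of 261.3 ± 63.3 (SD, n = 4). The high sum is therefore no measure of monocytes in that library. Heart library 2 was lowest in Ccl12 (55.3 against 101 to 111) and highest in Ltbp1 (1.94 against 0.934 to 1.01). Heart library 3 was highest in Cfb (12.01, with the lowest at 4.45) and lowest in Hspa1a (1614 against 1892 to 1930). Neutrophil markers summed to 69.1 RPKM in pericardial library 5 against 51.7 to 53.7, with the excess in Cxcr2 (24.3 against 3.69 to 5.86). Cxcr2, named after its values were seen, was also highest in peritoneal library 4 (33.7). Csf3r was level in the pericardial libraries (41.2 in library 5 against 41.1 to 42.6).

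The estimated exonic share of pericardial library 5 was 65.4%, against 83.4% to 86.3% in the other pericardial libraries, and peritoneal library 4 had the lowest share of any cavity library. Genomic DNA in these libraries was tested with vomeronasal receptor (Vmn1r) genes, which macrophages do not transcribe: their mean RPKM in peritoneal library 4 was 4.49 times the median of the other peritoneal libraries, which genomic DNA could explain and unspliced RNA of expressed genes could not. Lower depth was not seen by alignments, as peritoneal library 4 had 55.1 M, more than 2 of the other 3 peritoneal libraries. Alignments did not follow the read total behind RPKM. Relative depth read from the lowest RPKM values was 1.05 in peritoneal library 4, within the range of 0.933 to 1.41 in the other 3. Over the 12 cavity libraries the share fell with the log2 mean RPKM of olfactory receptor genes (r = -0.96, permutation p = 1e-05, the smallest possible; rho = -0.951, permutation p = 3e-05), with r = -0.935 without peritoneal libraries 4 and 3, the farthest from the median, in a family of 1 relation. No biological explanation was tested.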

How the results depend on the processing

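Of 280 pairs of a named gene and a comparison, 250 were called; 220 of these kept call and direction under each alternative that gave a value (the filter at RPKM 5 gave none for 26), 30 lost the call under at least 1, and 0 reversed. At an equal RPKM total the count for pericardial against heart was 6764, and 4343 of the 7698 genes kept call and direction; for pleural and peritoneal against heart it was 6398 and 6550, with 4276 and 5045 kept. For pericardial against pleural (2 genes) the count was 7 with a pseudocount of 0.1, 0 without the expression filter, 5 with median-ratio scaling, 4 with 2 groups only and 6 without the 2 cavity libraries of lowest exonic share; the cause was not tested. Fos lost its call there without the filter (adjusted p = 0.0597). Without it, calls lost included Fcrls (0.0549), Hspa1b (0.0653) in pericardial against peritoneal, Batf3 (0.074) in pleural against peritoneal and Ankrd37 set apart (0.0629). For pericardial against peritoneal (107) it was 253 with median-ratio scaling, 302 with quantile normalization, 477 at an equal RPKM total and 199 with the background covariate, which kept all 107; leaving out 1 library gave 60 to 117. For pleural against peritoneal (66) the values were 473, 559, 744 and 267, with 720 without the 2 cavity libraries of lowest exonic share, and 39 to 490 with 1 library left out (without pleural library 5 and without peritoneal library 4). Genes set apart in peritoneal cells (25) numbered 42, 56, 65 and 47 in the same order, and 16 without those 2 libraries. The cause of these shifts was not tested.

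Lists called with an estimated correlation numbered 0 in each of the heart comparisons, 0 in pericardial against pleural, 1 in pericardial against peritoneal and 2 in pleural against peritoneal, from 16, 15, 16, 7, 12 and 15. The mixed fry test called 26, 25 and 27 in the heart comparisons (pericardial, pleural, peritoneal), 1 in pericardial against pleural and 9 in pleural against peritoneal. The directional fry test called 25 in pleural and 25 in peritoneal against heart, 0 in pericardial against pleural, 3 in pericardial against peritoneal and 2 in pleural against peritoneal. With all genes above 0, correlations were 0.993 between pericardial and pleural, 0.989 between pericardial and peritoneal, 0.920 between pericardial and heart, 0.994 among pleural, 0.990 between pleural and peritoneal, 0.922 between pleural and heart, 0.914 between peritoneal and heart and 0.984 among heart libraries.

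Of the 250 called pairs of a named gene and a comparison, 0 reversed. Reversals were counted for named genes only, here and in what follows. Uncalled genes that changed sign were, in pericardial against pleural, Cd74 (-0.0877 with quantile normalization, -0.0609 at an equal RPKM total, -0.410 with the background covariate), H2-Aa (-0.0289, -0.0438 and -0.420), Icam2 (-0.0295 with quantile normalization and -0.0321 with the covariate) and Timd4 (-0.0163 with quantile normalization and -0.0125 at an equal RPKM total). In pericardial against peritoneal they were Timd4 (-0.143 with quantile normalization and -0.157 at an equal RPKM total) and Ctss, used only here (-0.0191 with quantile normalization). Leaving out 1 library moved uncalled genes across 0: in pericardial against peritoneal Adgre1 (-0.2064 without peritoneal replicate 4 to 0.0252) and Gata6 (-0.161 without peritoneal replicate 4 to 0.0945), in pericardial against pleural Cd74 (-0.219 to 0.449), H2-Aa (-0.225 to 0.494), Saa3 (-0.3111 without pericardial replicate 3 to 0.132) and Timd4 (-7e-04 to 0.276), and in pleural against peritoneal Timd4 (-0.207 to 0.0693). The replicate number as a block gave 5821 higher and 1593 lower in pericardial against heart, 60 and 49 in pericardial against peritoneal and 36 and 44 in pleural against peritoneal, where Fos lost its call (adjusted p = 0.0719). Of 24 pairs with the same number, 14 correlated above 0.1 (-0.627 to 0.63), and 7 of 16 libraries were closest to their own number. Only between pericardial and pleural libraries did all 4 pairs, so the number was taken as a pairing there alone. The replicate block in these 2 groups called 23 genes against 2 in the block fit of 16 libraries, and 0 with the background as a covariate beside the block. Libraries of different numbers could correlate more strongly, as pericardial library 5 with peritoneal library 4 (0.848), the cavity libraries of lowest exonic share. A low same-number correlation therefore does not exclude pairing in the other groups. Some measures followed the number in all 4 groups, as seen after the values were known. The B cell marker sum was highest in number 2 and lowest in number 5 of each group, and Siglec1, Ifit2 and Ifit3 were highest in number 3. Their chance rate was not computed, so they leave open whether the number pairs libraries in the other groups. Fits without a block ignore such an effect.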

Other observations

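Several gene groups differed between cavity populations without a called member. In pleural against peritoneal cells, 30 cell cycle genes had a median log2 fold of -0.40 with 0 called by limma (5 lower adjusted over the list alone; camera adjusted p = 2.63e-09; adjusted p = 0.613 with an estimated correlation). Oxidative phosphorylation genes were higher by camera in pericardial (adjusted p = 1.61e-05; adjusted p = 0.833 with an estimated correlation) and in pleural cells (0.000124; adjusted p = 0.818 with an estimated correlation) than in peritoneal cells. Between pericardial and pleural cells, 25 interferon response genes had a median of -0.21 (camera adjusted p = 2.09e-07; adjusted p = 0.863 with an estimated correlation), a call lost without pleural library 3 (camera adjusted p = 0.256, median 0.02), and cholesterol synthesis genes lay the other way (0.00045; adjusted p = 0.863 with an estimated correlation). Globin transcripts varied within the pericardial group, with Hbb-b1 at 438, 248, 71.9 and 31.5 RPKM in libraries 2 to 5.

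The tests of explanations for the immediate early genes, all tests of heart transcripts in pleural libraries, the list tests without pleural library 3, and the exchanges within pairs were chosen after seeing the result. Immediate early and heat shock genes were higher in heart and, more weakly, in pericardial than in peritoneal libraries. The median log2 fold of pericardial against heart was -3.82 at an equal RPKM total. This test of scaling could not have come out otherwise, as an equal total raises heart against pericardial values. RPKM totals ranged from 227397 to 482872, far less than such a fold. Genomic DNA was excluded for the heart level, as the median heart RPKM of the list was 7103 times the heart mean of olfactory receptor genes. Neither test addressed pericardial against peritoneal libraries. Handling of the cells before lysis could not be told from a difference in living tissue, as population and handling coincide. Of the genes, 92% (23 of 25) were higher in every heart library than in every cavity library. Chance gives this order for 0.0549% of genes where groups do not differ, and the share of all genes with it was not computed. The limit of handling holds for every other gene that differed between heart and cavity libraries, chemokine genes and Cd83 among them.

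Transcripts of heart libraries appeared at a low level in every pleural library. This pattern replaced a test of cardiomyocyte and fibroblast transcripts in heart libraries, which was run first. Of 11 genes with at least 10 RPKM in heart and at most 0.1% of that in pericardial and peritoneal means, 8 were higher in every pleural library than in the other cavity libraries. As the genes were chosen for low values in those libraries, this order has no chance rate. The 7 that are not cardiomyocyte markers had a median of 0.227% of the heart mean and the 4 cardiomyocyte markers 0.175%. By the limits set, these medians alone favoured heart RNA or reads mixed into the pleural libraries over cardiomyocytes in the lavage. Of the 7, muscle genes (Csrp3 and Cox8b) and genes that pleural macrophages could transcribe themselves (Fosb, Ccl12 and Cyr61) cannot decide. Cd207 and Slco2b1, at 0.157% and 0.182%, lay near Myl2 (0.188%) and Mb (0.192%). As they were found in libraries of sorted heart macrophages, transcription by pleural macrophages was not excluded for them either. With no clearly deciding gene the explanations cannot be told apart. Csrp3, Cox8b, Cyr61, Cd207 and Slco2b1 are named after their values were seen. The definition was tried in 3 forms, which gave 11, 9 and 20 genes with medians of 0.188%, 0.182% and 0.263%.

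Regroupings asked whether chance can be excluded. For genes, 1 of 35 splits of 8 libraries, the real one, called as many in pericardial against heart (7698, highest other 3930), pleural against heart (6933 and 1), peritoneal against heart (7071 and 6144) and pleural against peritoneal (66 and 1). In pericardial against pleural 1 of 35 did as well (2 and 0), but free splits ignore the pairing of these libraries. Pairing was not excluded in the other comparisons, and free splits would ignore it there too. Exchanges of labels within the 4 pairs leave 8 regroupings, too few to exclude chance, and in the blocked fit 2 of 8 called as many (23, highest other 480). The exchange of number 5 gave 480. It matched the background, which was lower in the pericardial library of pairs 2, 3 and 4 and higher in that of pair 5. With the background as a covariate the real labels called 0, the exchange of number 5 called 1, and that of numbers 3 and 5 called 5. In pericardial against peritoneal 3 of 35 did (107, highest other 1036), so chance could not be excluded. The split with 1036 set pericardial libraries 2, 3 and 4 and peritoneal library 3 against the others and followed the background, and with the background as a covariate the real split gave 199 and the highest other 0. With this covariate the real and highest other values were 6026 and 0 in pericardial, 6859 and 1 in pleural and 6543 and 2237 in peritoneal against heart, 3 and 0 in pericardial against pleural and 267 and 11 in pleural against peritoneal. Splits with as many lists numbered 10 (16, highest other 18), 14 (15 and 18), 11 (16 and 19), 20 (7 and 15), 3 (12 and 12) and 5 (15 and 15) of 35, in the order of the comparisons pericardial, pleural and peritoneal against heart, pericardial against pleural, pericardial against peritoneal and pleural against peritoneal, so chance could not be excluded for numbers of lists. For genes set apart, 1 of 100 regroupings gave as many for peritoneal (25, highest other 0) and for heart (5908 and 0). For pericardial (0 and 0) and pleural (0 and 0) the real count of 0 made all 100 of 100 as large, so this decided nothing.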
